A study of Mus musculus with 12 samples.

How the data were processed

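Small RNA sequencing was done on E14TG2a mouse embryonic stem cells, 3 untreated samples at day 0 and 3 samples after 6 days of retinoic acid. Total RNA sequencing was done on C2C12 cells, a mouse myoblast line, with 3 samples of undifferentiated myoblasts and 3 samples after 7 days of differentiation into myotubes. Per the labels' protocols, the small RNA was size-selected, depleted of the small ribosomal RNAs, treated with polynucleotide kinase and copied by a thermostable group II intron reverse transcriptase (TGIRT) that switches templates. The same protocols state that the total RNA libraries were made with a stranded, ribosome-depleting kit (TruSeq Stranded Total RNA Gold). No label says that samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

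The submitters' processing notes name bcl2fastq, Salmon 0.12.0, STAR 2.5.1b, featureCounts 1.5.1, DESeq2 1.18.1 and the genome build mm10, without saying which step each served. The deposited snoRNA table holds estimated counts, already rounded to whole numbers, for 72 families of box H/ACA snoRNAs named SNORA. A deposited key assigns 357 transcripts to these 72 families, of which 18 have 1 transcript and the largest pools 71, so copies of a family cannot be told apart. A second deposited snoRNA table holds normalised counts (a scaled signal). They equal the estimated counts multiplied by a factor that differed between libraries and, within each library, between families. The deposited C2C12 table holds raw counts for 55385 genes under Ensembl identifiers with gene symbols and lengths. Its normalised counterpart is the raw count times 1 factor per library, from 0.522 to 1.89, checked over genes with more than 50 counts. Of the 55385 identifiers, 54487 were found in the reference gene name table. Strand settings of the counting were not given in the sources used here, so overlapping and antisense genes are uncertain, as are near-identical copies.

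Tests were run on the deposited estimated counts, which needed no further rounding, and on the raw counts. The normalised tables were used only to describe the authors' scaling and, for the snoRNA families, in an alternative described with the other settings. In each cell system, edgeR 4.0.16 under R 4.3.3 was used with TMM scaling, filterByExpr by group, and the robust quasi-likelihood F-test, with no covariate. P-values were adjusted by the Benjamini-Hochberg method, and "adjusted p" without another name refers to this test at a threshold of 0.05. Standard errors (SE) of log2 fold changes were taken as the absolute log2 fold change divided by the square root of F. Levels are TMM-normalised CPM (library-scaled counts), as mean ± SD over 3 libraries. Gene lists fixed before the data were examined were tested with camera from limma 3.58.1, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Lists with at least 3 tested members entered, which gave 27 lists in C2C12 cells and 2 in the stem cells. Values of the snoRNA table are relative to the other SNORA families, so a rise or fall common to all box H/ACA snoRNAs would not be seen.

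Total estimated counts per snoRNA library were 4995747, 3743671 and 4404195 without and 2732639, 1706848 and 1496450 with retinoic acid. Filtering left 70 of 72 families. C2C12 totals were 54083215, 38640616 and 22200097 counts in myoblasts and 27273254, 31119511 and 18335785 in myotubes, and 15932 genes were tested. No pair of libraries agreed within sampling noise, with chi-square per degree of freedom of at least 104.1. Counting intervals and the floor of 3 counts used against a group total of 0 are at the 95% level, and they cover counting error only.

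Named snoRNA families were every tested member of the pre-rRNA cleavage list, plus up to 10 called families per direction with the largest fold change and no overlap between groups. Named C2C12 genes were of several kinds. They were the 5 genes per direction with the largest fold change among called genes of mean log2 CPM of at least 5 without overlap, leaving out predicted and mitochondrially encoded genes. They were also the 2 called members of each list with the highest mean level, the tested H/ACA ribonucleoprotein genes, and a set of myogenic factors fixed beforehand. Up to 3 called snoRNA genes per direction with the highest mean level were added. Other genes in the text were chosen after their values were seen, as members of the lists, unless stated.

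Same-numbered C2C12 samples deviated from their group means together, with correlations of 0.232, 0.189 and 0.17 over the tested genes. Each lay above 0.1, so the numbers were treated as a possible pairing, while the reported fits had no block. The differently numbered pair of myoblast replicate 3 and myotube replicate 2 had a higher correlation of 0.358. The pairing comes from the replicate numbers in the labels, which do not say what a number marks. A fit with the replicate number as a block was an alternative, and its value is given for C2C12 where it changes a call. In the stem cells, where the numbers did not pair the samples, only its counts of calls are given. Further alternatives were DESeq2 1.42.0, limma-voom, other scalings, other filters on low counts, an added fold threshold, fry, camera with an estimated correlation, and leaving out each library in turn. The planned scaling on box C/D snoRNAs was not run, since the table used here holds SNORA families alone.

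The steps were tested on counts simulated from the real means, library sizes and dispersions, in 20 runs per cell system. For C2C12, with 15932 genes of which 200 were changed per run, the test recovered 14% of the changes of 2-fold and 68.6% of those of 4-fold, and 8.21% of its calls were false. For the stem cells, with 70 families of which 14 were changed per run, it recovered 13.6% and 75%, and 7.46% of calls were false. Both false shares lie above the nominal 5%. The C2C12 runs changed 200 of 15932 genes, whereas 6386 were called in the data, so the C2C12 shares may not carry over. Camera called 0 of 400 lists of unchanged features in either system, and a list raised by known folds was called in 20 of 20 runs. The simulation took no correlation between genes from the data. It therefore cannot show whether the preset inter-gene correlation keeps false list calls low in the real data. A symbol-based RefSeq table for GRCm38.p6 supplied snoRNA lengths and host genes. Correlations used 100000 permutations, and figures were drawn with matplotlib.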

Results

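The series measured box H/ACA small nucleolar RNAs (snoRNAs) during retinoic acid differentiation of mouse embryonic stem cells, and gene expression during differentiation of C2C12 myoblasts into myotubes. Each of the 4 groups had 3 samples. Total counts ranged from 1496450 to 4995747 SNORA counts per stem cell library, with fewer in each library after retinoic acid, and from 18335785 to 54083215 gene counts per C2C12 library. The stated subject of the series is regulated snoRNA expression during differentiation, together with ribosomal RNA pseudouridylation and pre-ribosomal RNA processing. Only RNA levels are measured in the tables used here.

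Box H/ACA snoRNAs guide the conversion of uridine to pseudouridine, and a few act in pre-rRNA cleavage. After 6 days of retinoic acid, 5 of 70 tested SNORA families were higher and 11 were lower, relative to the other SNORA families after TMM scaling (edgeR, adjusted p under 0.05). SNORA43 fell from 4382 ± 293 to 230 ± 26.6 CPM (SD, n = 3), a log2 fold change of -4.25 ± 0.40 (SE, adjusted p = 3.11e-05). The log2 fold change was -3.07 ± 0.42 for SNORA1 (adjusted p = 0.000333), -3.06 ± 0.55 for SNORA4 (adjusted p = 0.00313) and -2.84 ± 0.54 for SNORA27 (adjusted p = 0.00313). Without retinoic acid replicate 1 they were -3.93 for SNORA4 and -3.54 for SNORA27. The abundant families SNORA44 and SNORA2 changed by -2.67 ± 0.33 and -1.74 ± 0.33, from 33591 ± 8655 and 45882 ± 11447 CPM without retinoic acid (SD, n = 3). SNORA67 changed by -2.21 ± 0.43, SNORA26 by -1.89 ± 0.49, SNORA15 by -1.81 ± 0.45 and SNORA57 by -1.68 ± 0.48. Without retinoic acid replicate 1 SNORA15 changed by -2.62, and with the authors' own factors, tried after seeing the data, SNORA26 by -3.14. SNORA33, named after its value was seen to complete the 11, changed by -1.52 ± 0.37 (SE).

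SNORA47 rose from 646 ± 122 to 2442 ± 407 CPM (SD, n = 3), a log2 fold change of 1.92 ± 0.44 (adjusted p = 0.00909). SNORA53 rose by 1.87 ± 0.48, SNORA54 by 1.70 ± 0.48, SNORA46 by 1.35 ± 0.36 and SNORA30 by 1.20 ± 0.34 on the log2 scale (SE). SNORA73, the U17 snoRNA of pre-rRNA cleavage and the only measured member of its list, stood at 53113 ± 10080 CPM before and 77032 ± 28493 CPM after (SD, n = 3), and was not called (log2 fold change 0.54 ± 0.41, adjusted p = 0.429). In 22 of the 70 families (31.4%) the groups did not overlap, against 10% by chance for 3 samples against 3.

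**Figure D1:**
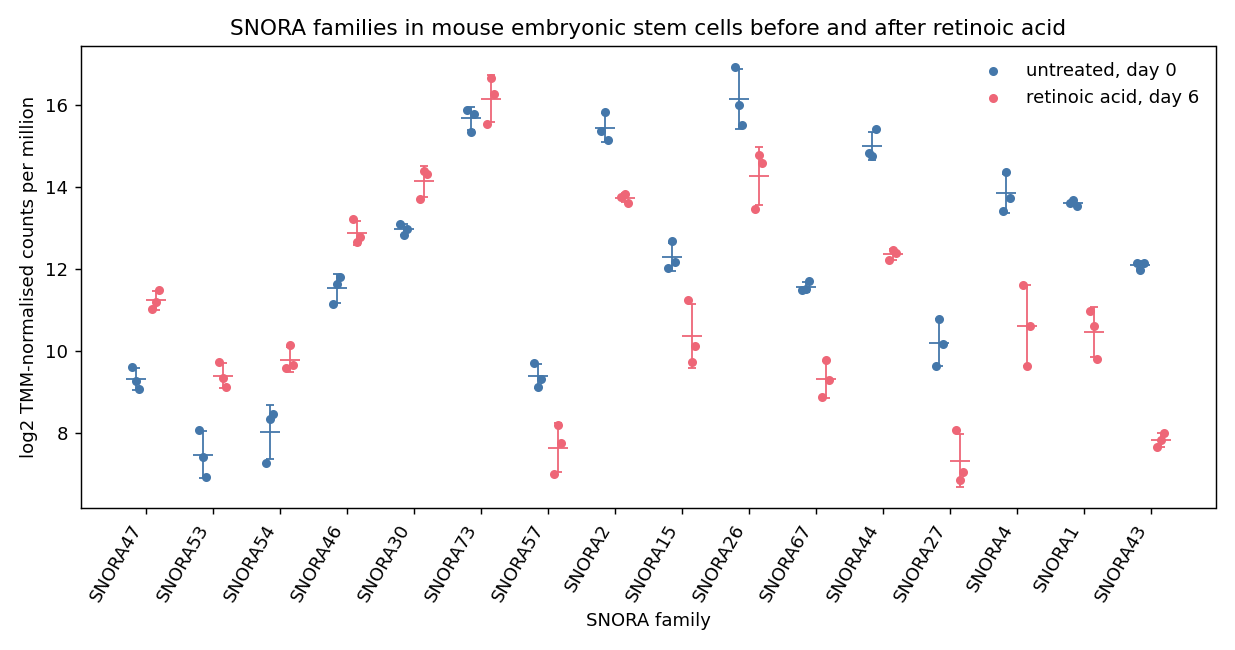
TMM-normalised CPM on a log2 axis for the 16 named SNORA families, with 3 untreated and 3 retinoic acid libraries as points, the mean as a line and the SD as bars. SNORA43 lies farthest apart between the groups (log2 fold change -4.25), while the groups overlap for SNORA73.

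Families that guide modification of the same ribosomal RNA moved in both directions. Of 14 tested guides of 18S rRNA, SNORA46 rose and SNORA44, SNORA67 and SNORA57 fell, the same 1 and 3 when adjusted over the list alone, and the list as a whole was not called (median log2 fold change -0.07, camera adjusted p = 0.546). Of 19 tested guides of 28S rRNA, SNORA54 rose and SNORA27 and SNORA33 fell, again 1 and 2 when adjusted over the list alone (median 0.42, camera adjusted p = 0.546). With an estimated correlation the adjusted p was 0.558 for both lists. Both lists were fixed beforehand and may be incomplete as sets of guides. The called families SNORA43, SNORA1, SNORA4 and SNORA2, among others, were on neither list, so their target RNA was not considered. Lists of box C/D snoRNAs, small Cajal body RNAs, imprinted snoRNA clusters and telomerase RNA had 0 members among the 72 families, so they were not analysed here.

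The number of families called depended on single libraries. Without untreated replicate 1, 2 or 3 in turn the test called 2, 0 and 0 families higher and 8, 9 and 8 lower, with 23, 17 and 17 families at an unadjusted p under 0.05. Without retinoic acid replicate 1 it called 15 higher and 20 lower, without replicate 2 it called 3 and 11, and without replicate 3 it called 3 and 8. SNORA43, SNORA1, SNORA4, SNORA27, SNORA44, SNORA67 and SNORA2 stayed called in all 6 of these runs. The call of SNORA47 was lost without untreated replicate 2 (adjusted p = 0.0908) or 3 (0.0719), and that of SNORA53 without the same libraries (0.152 and 0.104). SNORA46 was lost without untreated replicate 1, 2 or 3 (adjusted p = 0.0895, 0.157 and 0.095). SNORA54 and SNORA30 were kept only when retinoic acid replicate 1 was the library left out, with adjusted p of up to 0.152 and 0.157 otherwise, both without untreated replicate 2. SNORA26 was lost without untreated replicate 1 (adjusted p = 0.0895) or retinoic acid replicate 3 (0.0525), and SNORA57 without untreated replicate 1 (0.104), untreated replicate 3 (0.067) or retinoic acid replicate 3 (0.075). SNORA15 was lost without untreated replicate 1, 2 or 3 (adjusted p = 0.0519, 0.0963 and 0.104) or retinoic acid replicate 3 (0.0657), and SNORA33 without untreated replicate 2 (0.0543) or 3 (0.0696). Scaling by library size alone ended the calls of SNORA33 (adjusted p = 0.0507), SNORA54 (0.0684), SNORA46 (0.0905) and SNORA15 (0.0905), and leaving out the most abundant family those of SNORA46 (0.0554) and SNORA15 (0.069).

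In C2C12 cells, which fuse into multinucleate myotubes when differentiated, 3264 of 15932 tested genes were higher and 3122 lower in myotubes at day 7 (edgeR, adjusted p under 0.05), 40.1% of those tested. The groups did not overlap for 55.9% of genes, against 10% by chance. Of the called genes 51.1% were higher, against 42.1% (2678 higher, 3678 lower) when libraries were scaled by size alone, which moved the median log2 fold change of all genes by -0.125. Among called genes with a mean log2 CPM of at least 5, the named genes with the largest rises were Dmd (dystrophin), Lum (lumican), Mybpc2 and the myosin heavy chain genes Myh2 and Myh4. Myh4 rose from 0.302 ± 0.117 to 605 ± 32.5 CPM (SD, n = 3), a log2 fold change of 11.04 ± 0.37 (adjusted p = 1.39e-05), and Myh2 by 11.14 ± 0.87. Dmd had 1 count in all myoblast libraries and 7095 in myotubes, a ratio of 11800 with a 95% counting interval of 2110 to 464000. Mybpc2 had 3 counts against 4685, a ratio of 2590 (885 to 12500). The fitted log2 fold change of Dmd, 13.01, was 12.23 without myoblast replicate 1 and 14.58 without myoblast replicate 2, and that of Mybpc2, 11.20, was 12 without myoblast replicate 2. With limma-voom Dmd was at 12.29 and Myh2 at 10.52. Under the same limit on the mean level, the genes with the largest falls were Prl2c3, a prolactin family member, with -8.91 ± 0.78, the neurofilament genes Nefl (-7.98 ± 0.75) and Nefm (-6.39 ± 0.43), and the chromatin protein genes Hmga1b (-5.24 ± 0.28) and Hmga1 (-5.14 ± 0.30). Prl2c3 changed by -8.28 without myotube replicate 2 and by -9.71 without myotube replicate 3, and Nefl by -8.85 without myotube replicate 1. Prl2c3 and Hmga1b have near-identical copies, so their counts are uncertain.

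Genes of the contractile apparatus rose together. Of 46 tested sarcomere genes, 44 rose and Tpm3 fell, the same 44 and 1 when adjusted over the list alone, with a median log2 fold change of 7.37 (camera adjusted p = 2.33e-21, adjusted p = 0.32 with an estimated correlation). Ttn (titin) rose from 132 ± 51.3 to 9522 ± 4043 CPM and Neb (nebulin) from 7.81 ± 4.20 to 2404 ± 999 CPM (SD, n = 3). Myl2 had 0 counts in myoblasts and was at least 647-fold higher in myotubes, against a floor of 3 counts over the group, and the list's median was 7.37 with Myl2 at that bound as well. Of 21 tested genes of excitation-contraction coupling, 16 rose, and Fkbp1a and Clcn1 fell, also 16 and 2 over the list alone (median 5.74, camera adjusted p = 4.41e-07, adjusted p = 0.32 with an estimated correlation). The calcium-binding protein gene Casq2 rose by 8.57 ± 0.60 and Srl by 5.99 ± 0.50 on the log2 scale (SE), and Cacng6, at 0 in myoblasts, was at least 259-fold higher. Of 12 neuromuscular junction genes 9 rose, also 9 adjusted over the list alone (median 2.35, camera adjusted p = 2.2e-05, adjusted p = 0.32 with an estimated correlation), with the acetylcholine receptor subunit Chrna1 at 1.77 ± 0.41 and Lrp4 at 2.98 ± 0.21. Chrne, at 0 in myoblasts, was at least 142-fold higher, and Colq, with 2 counts there, had a ratio of 267 (95% interval 73.2 to 2210). Of 18 genes of muscle energy metabolism 12 rose, also 12 over the list alone (median 3.39, camera adjusted p = 2.39e-06, adjusted p = 0.32 with an estimated correlation), among them Pfkm (2.96 ± 0.34) and Mb, myoglobin (8.47 ± 0.75, or 7.77 without myoblast replicate 1). Ckmt2, at 0 in myoblasts, was at least 45.3-fold higher. With Cacng6, Chrne and Ckmt2 at their bounds the medians of these lists stayed at 5.74, 2.35 and 3.39. The median of excitation-contraction coupling was 4.98 without myotube replicate 1 and 5.05 without a filter on low counts, and that of energy metabolism 2.79 without myoblast replicate 3 or myotube replicate 3. Myotube replicate 1 had a lower sarcomere level than replicates 2 and 3 (median log2 CPM 7.33 against 8.26 and 8.30), and lower levels of the lists of excitation-contraction coupling (5.73 against 6.93 and 6.88), the neuromuscular junction (5.28 against 6.70 and 6.57) and energy metabolism (4.36 against 5.17 and 5.32).

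Among 24 tested myogenic regulators and fusion genes, 16 rose, and Myf5 and Lbh fell, with 17 and 2 when adjusted over the list alone (median 2.35, camera adjusted p = 3.04e-06, adjusted p = 0.423 with an estimated correlation). This list was lower in myotube replicate 1 than in replicates 2 and 3 (median log2 CPM 5.54 against 6.80 and 6.88), and without that library its median log2 fold change was 3.22. Myog rose by 6.08 ± 0.65, and the fusion genes Mymk and Mymx by 6.80 ± 0.62 and 7.20 ± 0.48 on the log2 scale (SE). Itga7 rose by 1.85 ± 0.30 and the cell cycle inhibitor gene Cdkn1a by 2.85 ± 0.46. Myf5 changed by -1.76 ± 0.30, while Myod1 was at 72.7 ± 32.4 CPM in myoblasts and 51.2 ± 31.1 in myotubes (SD, n = 3; log2 fold change -0.50 ± 0.57, adjusted p = 0.502). With the replicate block Myod1 was called lower (-0.67, adjusted p = 0.0457). Myf6 was near the detection limit (0.257 ± 0.146 against 0.908 ± 0.272 CPM), and its call (adjusted p = 0.038) was lost without myoblast replicate 1 or 3 (0.0634 and 0.0987) or myotube replicate 2 or 3 (0.0991 and 0.119).

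Cell cycle genes fell. Of 35 tested mitosis genes 34 fell (median -2.77, camera adjusted p = 3.07e-14, adjusted p = 0.423 with an estimated correlation), and all 35 when adjusted over the list alone. Of 45 DNA replication genes 43 fell, and 44 over the list alone (median -2.44, camera adjusted p = 4.77e-21, adjusted p = 0.32 with an estimated correlation). Top2a (topoisomerase) was at 899 ± 41.7 CPM in myoblasts and 192 ± 191 in myotubes (SD, n = 3), a log2 fold change of -2.23, and Mki67 changed by -2.20 ± 0.52. Without a filter on low counts both calls were lost (adjusted p = 0.147 and 0.08). The ribonucleotide reductase genes Rrm2 and Rrm1 changed by -2.68 ± 0.23 and -1.78 ± 0.19. Myotube replicate 1 had a higher mitosis level than replicates 2 and 3 (median log2 CPM 5.18 against 3.75 and 3.20) and a higher DNA replication level (4.30 against 3.68 and 3.46), with Top2a at 412 against 90.3 and 73.8 CPM. Without this library Top2a changed by -3.47, Mki67 by -3.11 and the median of the mitosis list was -3.69. The call of Top2a (adjusted p = 0.0243) was lost without myoblast replicate 2 or 3 (0.0605 and 0.0586) or myotube replicate 2 (0.0636).

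**Figure D2:**
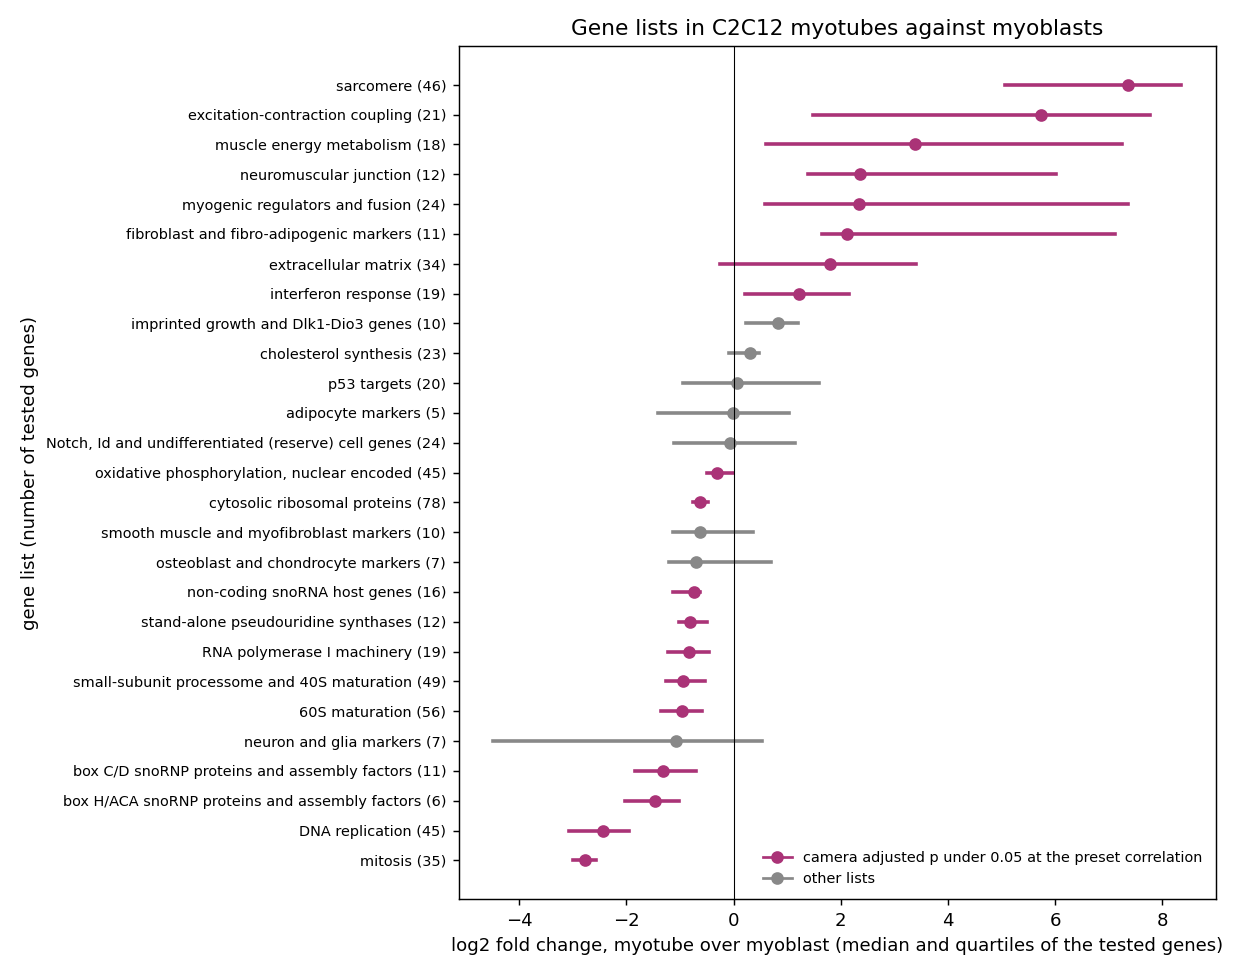
Median log2 fold change (points) and quartiles (lines) of the tested genes of 27 lists, myotube over myoblast, with the number of tested genes in brackets and colour for the camera adjusted p at the preset correlation. The sarcomere list lies highest (median 7.37) and the mitosis list lowest (median -2.77).

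Of 6 tested genes for the protein partners of box H/ACA snoRNAs, Dkc1, Nhp2, Gar1 and Shq1 fell, with 5 when adjusted over the list alone (median -1.47, camera adjusted p = 0.00533, adjusted p = 0.32 with an estimated correlation). Dkc1 (ENSMUSG00000031403.14), which encodes the pseudouridine synthase dyskerin, fell from 150 ± 49.4 to 25.9 ± 9.92 CPM (SD, n = 3), a log2 fold change of -2.53 ± 0.36 (adjusted p = 0.00136). The core protein genes Nhp2 and Gar1 changed by -2.08 ± 0.31 and -1.88 ± 0.35 (SE), and the assembly factor gene Shq1 by -1.01 ± 0.25 (adjusted p = 0.0144). The core protein gene Nop10 was not called (-0.31 ± 0.23, adjusted p = 0.297), except without myotube replicate 1 (-0.60, adjusted p = 0.0237). The assembly factor gene Naf1 was not called (-1.06 ± 0.38, adjusted p = 0.0563), but it was with the replicate block (adjusted p = 0.046) and without myoblast replicate 1 (0.00959). DESeq2 called it as well (0.0243), as did edgeR with library size scaling (0.0305) or no filter (0.017). Shq1 lost its call without myoblast replicate 2 or 3 (0.0507 and 0.0566). Of 11 box C/D ribonucleoprotein genes 9 fell, and 11 over the list alone (median -1.31, camera adjusted p = 4.41e-05, adjusted p = 0.32 with an estimated correlation), with Nop56 at -2.18 ± 0.34 and Nop58 at -1.73 ± 0.36. Myotube replicate 1 was lower than replicates 2 and 3 in the H/ACA list (median log2 CPM 3.12 against 3.88 and 3.64) and in the C/D list (4.17 against 4.66 and 4.43).

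Genes of ribosome assembly were lower too. Of 49 genes of the small-subunit processome and 40S maturation 31 fell, and 36 when adjusted over the list alone (median -0.95, camera adjusted p = 4.13e-09, adjusted p = 0.439 with an estimated correlation), with Wdr36 at -1.54 ± 0.25 and Utp20 at -1.78 ± 0.32. Of 56 genes of 60S maturation 35 fell, and 37 over the list alone (median -0.96, camera adjusted p = 4.13e-09, adjusted p = 0.439 with an estimated correlation). Among them Npm1 (nucleophosmin) fell from 1138 ± 387 to 314 ± 71.4 CPM (SD, n = 3), and Rsl1d1 changed by -0.96 ± 0.26. Of 19 RNA polymerase I genes 10 fell, and 11 over the list alone (median -0.84, camera adjusted p = 0.000402, adjusted p = 0.32 with an estimated correlation), with Ncl (nucleolin) at -1.55 ± 0.26 and Ubtf at -0.89 ± 0.25. Of 12 stand-alone pseudouridine synthases, enzymes that need no guide RNA, 7 fell, and 8 over the list alone (median -0.82, camera adjusted p = 0.00419, adjusted p = 0.439 with an estimated correlation), with Pus7 at -0.86 ± 0.29 and Pus10 at -0.78 ± 0.22. Some of these calls rested on single libraries. Pus7 was lost without myoblast replicate 2 or 3 (adjusted p = 0.0858 and 0.148) or myotube replicate 1 or 3 (0.0648 and 0.0905), and with a mean count of at least 50 required (0.0549). Pus10 and Rsl1d1 were lost without myoblast replicate 2 (0.061 and 0.051), myoblast replicate 3 (0.0787 and 0.0678) or myotube replicate 3 (0.057 and 0.0544), and Ubtf without myoblast replicate 1 or 3 (0.052 and 0.0614). In myotube replicate 1 the processome list was lower than in replicates 2 and 3 (median log2 CPM 4.67 against 5.37 and 5.34), as were the lists of 60S maturation (4.83 against 5.65 and 5.64) and pseudouridine synthases (3.15 against 3.42 and 3.41). The RNA polymerase I list was at 4.78 there against 4.74 and 4.74, with 6 of its 19 genes above the mean of the other myotube libraries, and Npm1 was at 393 against 298 and 253 CPM.

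Of 78 cytosolic ribosomal protein genes 23 fell, and 14 when adjusted over the list alone (median -0.62, camera adjusted p = 1.28e-08, adjusted p = 0.508 with an estimated correlation). Rpl4 changed by -0.89 ± 0.21 and Rpsa by -0.94 ± 0.31 (SE). The call of Rpsa (adjusted p = 0.0438) was kept only when myotube replicate 1 was the library left out. Its adjusted p was 0.0948, 0.0996 and 0.0702 without myoblast replicates 1, 2 and 3, and 0.123 and 0.128 without myotube replicates 2 and 3, and 0.0617 with a mean count of at least 50 required. The ribosomal protein level was higher in myotube replicate 1 than in replicates 2 and 3 (median log2 CPM 8.33 against 7.79 and 7.65). Of 16 non-coding snoRNA host genes 10 fell and Snhg18 rose, with 12 and 1 over the list alone (median -0.74, camera adjusted p = 0.000721, adjusted p = 0.423 with an estimated correlation). Snhg5 changed by -1.23 ± 0.19 and Gas5 by -0.73 ± 0.19, the latter with adjusted p = 0.0554 without myotube replicate 3.

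**Figure D3:**
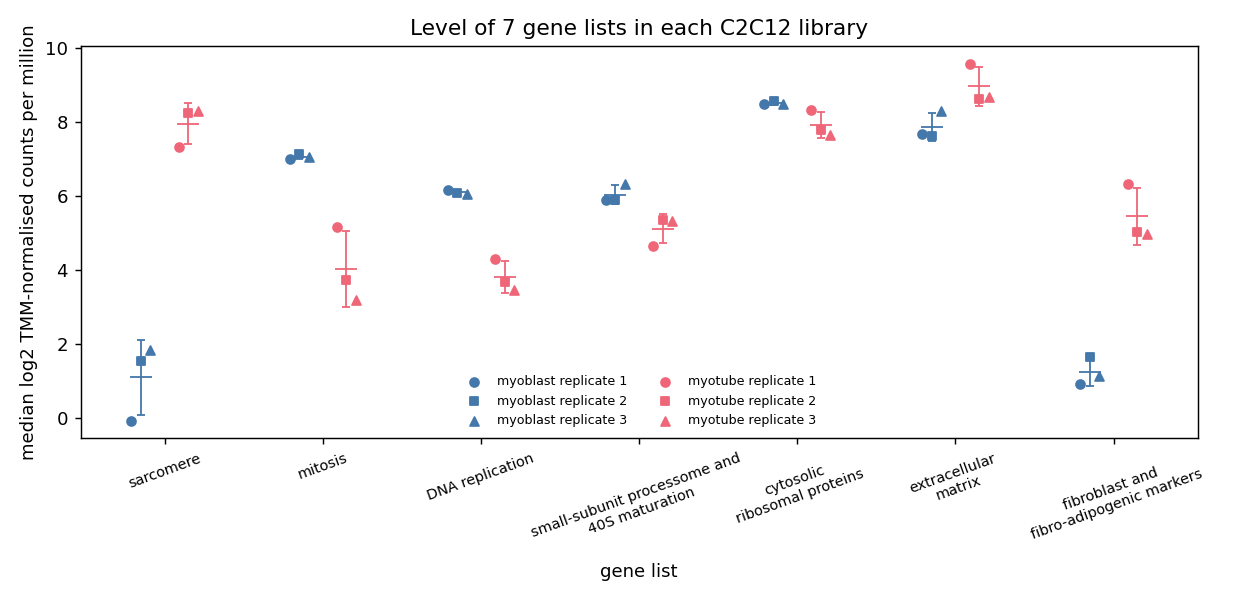
Median log2 TMM-normalised CPM of 7 gene lists in each C2C12 library, with marker shape for the replicate, the mean as a line and the SD as bars. Myotube replicate 1 lies apart from the other myotube libraries, for example at 5.18 against 3.75 and 3.20 for the mitosis list.

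Extracellular matrix and fibroblast marker genes were higher in myotubes. Of 34 tested matrix genes 23 rose, and Col4a1 and Loxl2 fell, with 23 and 4 over the list alone (median 1.81, camera adjusted p = 0.000178, adjusted p = 0.423 with an estimated correlation). Col3a1, a fibrillar collagen gene, rose by 3.32 ± 0.58 and Fn1 (fibronectin) by 2.05 ± 0.40 on the log2 scale (SE). Of 11 tested fibroblast and fibro-adipogenic markers 10 rose, also 10 over the list alone (median 2.12, camera adjusted p = 3.09e-05, adjusted p = 0.32 with an estimated correlation). Dcn (decorin) rose by 8.01 ± 0.97 and Gsn by 1.11 ± 0.35, the latter with adjusted p of 0.0881, 0.0698 and 0.127 without myoblast replicates 1, 2 and 3, and 0.0548 with library size scaling. Dcn and Lum belong to both lists, and Lum rose by 11.93 ± 1.67 from 0, 1 and 3 counts in the myoblast libraries, so its fold is imprecise. It was 9.72 without myotube replicate 1, 11.02 without myoblast replicate 1, 13.39 without myoblast replicate 3 and 10.97 with limma-voom. Without myotube replicate 1 Dcn rose by 6.78 and Col3a1 by 2.38. The median of the fibroblast list was 2.74 and 2.96 without myoblast replicates 1 and 2, 2.89 without myotube replicate 3 and 2.71 without a filter on low counts. Levels in myotube replicate 1 stood above the others, with Col3a1 at 24210 against 6352 and 6906 CPM and Lum at 379 against 32.7 and 31.8 CPM.

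Of 19 tested interferon response genes 8 rose and Oasl1 fell, with 9 and 1 over the list alone (median 1.21, camera adjusted p = 0.0111, adjusted p = 0.524 with an estimated correlation), and without a filter on low counts the median was 0.59. Ifi27 changed by 1.46 ± 0.28 and Ddx58 by 1.76 ± 0.44, or 1.15 without myotube replicate 1. This list was higher in myotube replicate 1 as well (median log2 CPM 2.75 against 1.95 and 1.96). Of 45 nuclear-encoded genes of oxidative phosphorylation 2 rose, among them Ndufa1, and 7 fell, with 0 and 2 over the list alone (median -0.30, camera adjusted p = 0.0143, adjusted p = 0.524 with an estimated correlation). Unadjusted p was under 0.05 for 15 of these genes. DESeq2 and limma-voom called 9 and 8 of them lower, and 0 and 2 higher, over all genes. Atp5b changed by -0.80 ± 0.22 and Atp5c1 by -0.49 ± 0.16, and the adjusted p of Atp5c1 was 0.0527 with the replicate block and 0.0799 without a filter. Atp5b was lost without myoblast replicate 2 or 3 (0.0781 and 0.0512) or myotube replicate 3 (0.0728). Atp5c1 was lost without myoblast replicate 2 or 3 (0.128 and 0.0876) or myotube replicate 2 or 3 (0.109 and 0.127). Mitochondrially encoded genes took 0.952% to 1.96% of counts in myoblast libraries and 4.52% to 5.68% in myotube libraries.

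The remaining lists were not called by camera. Of 10 imprinted growth genes 4 rose (H19, Igf2r, Snrpn and Cdkn1c) and Peg10 fell, with 5 and 1 over the list alone (median 0.83, camera adjusted p = 0.223). H19 rose from 688 ± 268 to 5096 ± 2065 CPM (SD, n = 3) and Igf2r by 1.25 ± 0.23 on the log2 scale. Of 24 genes of Notch and Id signalling and undifferentiated cells 7 rose and 7 fell, with 7 and 8 over the list alone (camera adjusted p = 0.587). Their median (-0.07) and the camera direction were down while their mean was 0.11. In myotube replicate 1 this list was lower than in replicates 2 and 3 (median log2 CPM 4.56 against 5.30 and 5.19). So were the lists of p53 targets (4.79 against 5.33 and 5.53) and cholesterol synthesis (5.82 against 6.91 and 6.25). The cyclin genes Ccnd1 and Ccnd3 changed by -3.58 ± 0.49 and 1.29 ± 0.25, with Ccnd1 at -4.39 without myotube replicate 1. Of 20 p53 target genes 8 rose and 5 fell, with 8 and 6 over the list alone (median 0.07, or -0.06 with library size scaling, camera adjusted p = 0.587), with Eda2r at 2.73 ± 0.33. Of 23 cholesterol synthesis genes edgeR, DESeq2 and limma-voom each called 0, over all genes, and edgeR also called 0 over the list alone (median 0.30, camera adjusted p = 0.587), with 2 at an unadjusted p under 0.05.

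Markers of other cell types gave mixed results, with the same counts when adjusted over the list alone. Of 7 tested neuron and glia markers Nefl, Tubb3, Stmn2 and Nefm fell (median -1.07, camera adjusted p = 0.0733), with Tubb3 at -2.59 ± 0.44. Of 5 adipocyte markers Cebpa rose, and Pparg (-1.40 ± 0.23) and Plin4 (-3.82 ± 0.63) fell (median -0.02, camera adjusted p = 0.587). Of 7 osteoblast and chondrocyte markers Spp1 (-1.19 ± 0.35) and Sox9 (-1.23 ± 0.30) fell (median -0.69, camera adjusted p = 0.311). Spp1 was lost without myoblast replicate 2 or 3 (adjusted p = 0.1 and 0.0813) or myotube replicate 2 or 3 (0.0565 and 0.0827). Of 10 smooth muscle and myofibroblast markers Mylk and Des (1.83 ± 0.40) rose, and Tpm4 (-1.19 ± 0.28), Actg2 and Cnn1 fell (median -0.63, camera adjusted p = 0.644). Of the endothelial and blood cell markers only Cd68 passed the filter, and it was not called (-0.55).

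Small nucleolar RNA genes were also counted in the C2C12 libraries, which were not size-selected for small RNAs. There were 150 such genes, of which 40 were tested. Scarna6 (1.35 ± 0.44) and Snora30 (1.77 ± 0.50) were higher, and Snord43 (-1.34 ± 0.44), Snord49a (-1.28 ± 0.44), Snord55 (-1.46 ± 0.45) and Snord42b (-1.81 ± 0.49), named after its value was seen, were lower (log2 fold change ± SE, edgeR, adjusted p from 0.0196 to 0.0473). Snora30 had 7 to 35 counts per library. Adjusted over the list alone, 0 were called in either direction, with 13 at an unadjusted p under 0.05. Over all genes DESeq2 called 6 higher and 5 lower, and limma-voom 4 and 4. With the replicate block 5 were higher, and Snord49a was not called (adjusted p = 0.0616). Library size scaling ended the call of Scarna6 (0.0738), and a mean count of at least 50 that of Snord49a (0.0576). Without myoblast replicates 1, 2 and 3 in turn the counts were 5, 1 and 1 higher and 1, 2 and 1 lower. Without myotube replicate 2 edgeR called 0 higher and 1 lower, with 3 and 6 at an unadjusted p under 0.05. Without myotube replicate 3 it called 2 higher and 0 lower, with 7 and 5. The named snoRNA genes each lost their call in 4 to 6 of the 6 runs without a library, with adjusted p of up to 0.112. Snord42b lost it without myoblast replicate 3 (0.0704) or myotube replicate 2 or 3 (0.0515 and 0.0866).

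Across the 13 SNORA families measured in both systems, the log2 fold changes after retinoic acid and in myotubes had Pearson's r of 0.405 (permutation p = 0.166) and Spearman's rho of 0.462 (permutation p = 0.115), both 2-sided and both 0.166 after adjustment over the 2 relations. SNORA73 was represented by Snora73b (0.99 in myotubes), the more abundant of its near-identical copies. With Snora73a (-1.03) in its place, tried after the values were seen, r was 0.335 (permutation p = 0.272) and rho 0.242 (permutation p = 0.425). Without the 2 families farthest from the median on the stem cell axis r was 0.247 (permutation p = 0.47). The relation is across genes, which are not independent replicates. SNORA30 was called higher in both systems, but without single libraries it lost its call in 5 of 6 stem cell runs and 4 of 6 C2C12 runs.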

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

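SNORA35 had 29 estimated counts in retinoic acid replicate 1 (10.6 CPM of that library, without TMM scaling) and 0 in the other 5 libraries, where a count of 0 allows up to 3 counts for counting error alone. It stood out as a signal in a family that was not tested and that was at 0 in every untreated library. Dixon's outlier test was not run, since each group has 3 samples.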

How the results depend on the processing

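The scaling by the authors' own factors, the run without untreated replicate 2 and retinoic acid replicate 1, the run without genes holding rRNA repeat reads, and Snora73a in place of Snora73b were chosen after seeing the data. No named gene or family reversed its direction where a call was involved, in any setting, and causes of changed calls were not tested. The count of SNORA families higher, 5 as reported, was 3 with library size scaling, 8 with DESeq2, 7 with the authors' factors, 8 (with 16 lower) without untreated replicate 2 and retinoic acid replicate 1, where SNORA53 was lost (adjusted p = 0.13), and 0 to 15 without single libraries (unadjusted p under 0.05 for 17 families in each run with 0). The count lower, 11 as reported, was 8 to 20 without single libraries. In the stem cells same-numbered samples did not deviate together (correlations -0.638, -0.458 and 0.049). With the replicate number as a block 1 family was higher and 8 lower, and no sample pair with the same number had the highest correlation. For C2C12, adding a 2-fold threshold left 2524 higher and 1923 lower genes. Other settings gave 2430 to 3908 higher and 2127 to 3678 lower. With the replicate block 3561 genes were higher and 3322 lower. The block changed no named call other than those of Atp5c1, Naf1, Myod1 and Snord49a, and no list call. Of 75 named C2C12 genes, 55 kept their side of the threshold without each library in turn, and list calls did so for all 27 lists. SnoRNA genes higher in C2C12, 2 as reported, were 1 with library size scaling, 5 with the block and 0 to 5 without single libraries (edgeR, 3 at an unadjusted p under 0.05 in the run with 0). Those lower, 4 as reported, were 2 with a mean count of at least 50 and 0 to 4 without single libraries (5 at an unadjusted p under 0.05 in the run with 0). With an estimated correlation camera called 0 of the 27 lists, against 19 with the preset value, at medians of 2.35 (myogenic regulators), 7.37, 5.74, 2.35, 3.39, -2.77, -2.44, -1.47, -1.31, -0.82, -0.95, -0.96, -0.84, -0.62, -0.74, 1.81, 1.21, -0.30 and 2.12, in the order of the lists of sarcomere, excitation-contraction coupling, neuromuscular junction, energy metabolism, mitosis, DNA replication, H/ACA and C/D ribonucleoproteins, pseudouridine synthases, processome, 60S maturation, RNA polymerase I, ribosomal proteins, snoRNA hosts, matrix, interferon response, oxidative phosphorylation and fibroblast markers. By fry, which does not compare a list with other genes, the ribosomal protein (-0.62), interferon (1.21) and oxidative phosphorylation (-0.30) lists were not called (adjusted p = 0.0602, 0.0602 and 0.066), while the imprinted (0.83) and neuron (-1.07) lists were (0.0158 and 0.00231). Scaling on box C/D snoRNAs was not run, since the SNORA table gives no such value. At the depth of these libraries 40 of 150 snoRNA genes in C2C12 had enough counts to pass the filter, and the others were left out of the reported test.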

Other observations

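The tests of incomplete response, of the highest of 9 pairs and library depth for retinoic acid replicate 1, all tests on myotube replicate 1, and the gene groups and single genes of the next paragraph were chosen only after the results were seen. The test of mitosis genes below replaced a first version that had left the question undecided.

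Of 7 further gene groups in C2C12 cells, none was called with an estimated correlation (adjusted p from 0.187 to 0.423). All 7 tested replication-dependent histone genes were lower (median log2 fold change -3.02, camera adjusted p = 0.00038, adjusted p = 0.259 with an estimated correlation), as were 17 of 19 nuclear pore genes, with 1 higher (median -1.31, 2.03e-07 and 0.187), and 43 of 77 mitochondrial ribosomal protein genes (median -0.59, 2.17e-08 and 0.187). Of 10 mitochondrially encoded protein genes 7 were higher (median 1.26, 0.00186 and 0.302). Of 17 aminoacyl-tRNA synthetase genes 10 were lower (median -0.60, 0.000462 and 0.302), and of 35 proteasome genes 8 (median -0.47, 0.000462 and 0.423). All 3 tested prolactin family 2c genes, near-identical copies, were lower (median -8.98, 0.000498 and 0.187). Outside the lists, the fatty acid transporter gene Cd36 rose by 7.15 ± 0.25, Fgf21 by 6.38 ± 0.30 and Hsd11b1 by 9.02 ± 0.47 on the log2 scale (SE). Igfbp2 changed by -4.01 ± 0.23 and Itgb7 by -6.73 ± 0.45, or -7.57 without myotube replicate 1.

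Myotube replicate 1 lay apart from replicates 2 and 3, with mitosis genes higher in 35 of 35 (median log2 difference 1.68), ribosomal protein genes in 78 of 78 and sarcomere genes in 0 of 46. A mislabelled myoblast library is excluded by 44 of 46 sarcomere genes above every myoblast library. Undifferentiated myoblasts in the culture are argued against as the source of the processome deviation, since 31 of 31 genes that fell in myotubes were lower still there (median -0.774). Those 31 were called in a fit that includes this library, and over the whole list 1 of 49 genes was higher there (median -0.697). Myoblasts that were present but outweighed by lower levels in the other cells are not excluded. Whether undifferentiated myoblasts were the single source of the mitosis signal was not decided. Mitosis genes implied a myoblast share of 20.4% (quartiles 14.3 to 26.6) and DNA replication genes 8.1% (3.2 to 13.3). The first version, over 304 other genes high in myoblasts, gave 15% (3.9 to 23.1) and overlapped. The quartiles are spreads across genes of a single library, so their narrow gap does not settle the share. More fibroblast-like cells stay open. The fibroblast marker list lay 1.185 higher on the log2 scale, above all of 10000 matched random lists, as did the matrix list. The lists of mitosis, DNA replication, ribosomal proteins and interferon response reached the same rank, so it is not particular to fibroblast markers. Col3a1 was at 24210 and Dcn at 1677 CPM. However, 7 of the 11 fibroblast markers had a myoblast mean of at least 1 CPM, and their list shares Dcn and Lum with the matrix list. No other biological explanation was tested.

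Retinoic acid replicate 1 lay apart from replicates 2 and 3, showing a median of 0.438 (quartiles -0.002 to 0.844) of the change of the 35 families called without it, with 26 in the same direction. Those families were picked on replicates 2 and 3, which by itself lowers the share in replicate 1, and no comparable share was computed. An incomplete response as the whole cause was tested on the 35 families not called without retinoic acid replicate 1, and was not decided. There the deviation of that library followed that of untreated replicate 2 from the other untreated libraries (r = 0.833, 95% bootstrap interval 0.706 to 0.931, and 0.919 given the response). The response was built from the same reference libraries as both deviations, so the value of 0.919 is partly built in. Choosing families with little response also ties the reference means together, which can raise the r of 0.833. Families that were not called may still have responded, since the simulated stem cell test recovered 13.6% of 2-fold changes. The interval does not cover the choice of the pair. This pair of libraries was picked as the highest of 9, and a permutation test of the highest of 9, across families, which are not independent replicates, gave p = 1e-05, the smallest possible, with the next pair at r = 0.54. Whether unequal totals caused this relation could not be decided. Thinning all libraries to the smallest total left r at 0.871 over 70 families, against 0.873 before. Thinning hardly alters families with many counts, so r was likely to stay in either case. An effect of depth that arose before the counting stays open, since thinning cannot undo it. SnoRNA length stays open as well, since 37 of 70 families (52.9%) had a length where 80% were needed (rho = -0.254, permutation p = 0.131). What the 2 libraries share stays open, and no other biological explanation was tested.

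Among the 40 snoRNA genes tested in C2C12 cells, longer genes had higher log2 fold changes (Spearman's rho 0.517, permutation p = 0.00067, across genes, which are not independent replicates). A difference in fragment length between the groups that acts on all short annotated genes is argued against by 592 other genes. These were of at most 500 bases, with rho of -0.283 (95% bootstrap interval -0.357 to -0.206, permutation p = 1e-05, the smallest possible). Of these, 156 of at most 200 bases, the range of most of the snoRNA genes, gave -0.006, so there the relation was absent rather than reversed. Reads of these genes may come from molecules longer than the annotation, which was not checked. A fragment length effect on intact small RNAs alone therefore stays open. Length also differed between the snoRNA classes, with median log2 fold changes of -0.802 (Snord), -0.513 (Snora) and 0.537 (Scarna), and the 2 were not told apart. Reads from host gene introns cannot be told apart from snoRNA reads by the relation of 33 intronic snoRNAs to their 27 host genes (rho = 0.18, 95% bootstrap interval -0.173 to 0.477, permutation p = 0.317). No biological explanation was tested.

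The hypothesis that SNORA families of 1 host gene change together after retinoic acid could not be decided. Of the 7 families with a shared host in the annotation, 6 pool several transcripts, up to 71, so their values cannot be assigned to that host. Over these 7 families of 3 hosts the mean absolute difference within a host was 3.022 on the log2 scale, above the median of 2.326 of 10000 random regroupings (permutation p = 0.831).

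The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. In the stem cells 1 split, the real one, gave 16 calls (26 at an unadjusted p under 0.05) and the other splits gave at most 0 (edgeR, 18). Every other split puts both states in each group, which raises the spread, so few calls there decide nothing. The split with 18 set untreated replicate 1 and retinoic acid replicates 2 and 3 against the rest, among them untreated replicate 2 and retinoic acid replicate 1. In C2C12 cells 1 split, the real one, gave 6386 calls (7989) and the others at most 0 (638), including the 3 that also part all 3 pairs but mix myoblasts and myotubes in each group.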
